A study of Mus musculus with 8 samples.

How the data were processed

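The series holds 8 mouse RNA sequencing libraries in 4 groups of 2. Per the labels, 2 groups are CD4 T cells flow sorted as naive (CD44 low) from wild type (WT) mice or from mice lacking the complement C5a receptor C5aR1 (KO). The remaining 2 groups are CD4 cells sorted as CXCR5 positive and PD1 high, the surface pattern of T follicular helper (TFH) cells. These came from spleens of (bxd)F1 mice 7 days after they had received WT or KO donor spleen cells depleted of CD8 cells. Transfer of parental T cells into an F1 host is a standard way to induce graft-versus-host disease. Total RNA was extracted with a spin-column kit and sequenced as single-end reads of 51 bp, per the labels' protocols.

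Per the submitters' processing notes, BWA (an aligner) and the mouse build mm10 were used, with no version given. The counting tool, the gene annotation, any filter on low genes and the normalization are not given in the sources used here. The authors deposited 1 table per library with 14042 gene symbols and a log2 expression value for each. The deposited log2 values run from 1.16 to 19.48. The sorted values of each library lie within 0.03 of the median library above the lowest percentile, so the values had been quantile normalized across the 8 libraries before deposit; ties differ more below it. Raised to the power of 2, they add up to the same total in every library, which is set by that step and is not a sequencing depth. Steps of whole reads cannot be looked for after such normalization. The depth of each library is unknown and no counting interval is given. Quantile normalization also removes any difference between libraries in the overall spread of expression.

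The design fixed before the data were examined had assumed read counts, with limma on log2 of the value plus 1 for other units. The deposited values are already on a log scale, so the linear model of limma 3.58.1 (R 4.3.3) was fitted to them as they stand, with no pseudocount. All 14042 genes and all 8 libraries entered 1 model with a mean per group, which leaves 4 residual degrees of freedom. Standard errors were moderated with a mean-variance trend and the robust option. The trend setting was chosen after results with and without it had been seen, and counts without it are among the alternatives. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p below 0.05. A log2 fold change is the difference of group means, given with its moderated standard error (SE). The labels do not say that the libraries of a group came from separate animals. P-values therefore measure the spread between these samples, which may be technical. The naive KO libraries differ in sex-linked genes, given below, so those 2 are not copies of 1 sample. Replicate numbers follow the order of deposit and pair nothing. An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.33.

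There were 5 comparisons: KO against WT in TFH-labelled and in naive-labelled libraries, TFH-labelled against naive-labelled libraries in WT and in KO, and the interaction of genotype and label. Of the gene lists fixed before the data were examined, 25 had at least 5 measured members. Mitochondrially encoded genes were not analysed here. Lists were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance or, in its mixed test, change in either direction. Calls within a list were also counted after adjustment over the list alone. On simulated data with 200 changed genes among the 14042, the model recovered 58% of genes changed by a log2 of 1 and 89% of genes changed by 2 between KO and WT TFH-labelled libraries. It recovered 0% at a log2 change of 0.5. For the interaction the recovery was 28% at 1 and 87% at 2. The simulated noise was independent between genes, without shared shifts between libraries such as that of the B cell genes below. These rates may therefore not hold for the real libraries.

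The genes named were set by a rule written before the data were examined. For each comparison it takes the 10 called genes with the largest rise and the 10 with the largest fall, at a level of at least log2 7.96 (a set share of the summed linear values) in the higher group. Both libraries of one group had to lie above both of the other, except for the interaction, and predicted or numbered genes and antigen receptor segments were left out. It adds up to 4 called members of each list by p, or the 2 with the smallest p where none was called. It also adds a fixed set in every comparison: Bcl6, Cxcr5, Pdcd1, Icos, Il21, Prdm1, Ccr7, S1pr1, Klf2, Foxp3, Myc and Mki67. That set also held C5ar1, C5ar2 and C3ar1, which were not analysed here, and 1 gene that is not reported here. The text leaves out part of the top and list genes for length. Gene positions are those of GENCODE vM21 and RefSeq on GRCm38, the build that mm10 names.

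Alternatives fixed in advance were a fit without the robust option, a filter at that level in 2 libraries (11381 genes kept), a fit with the compared groups only, stricter thresholds, and leaving out each library in turn. Where a group then has 1 library, that library is assumed to vary like the others. Another 5 alternatives were chosen after seeing the data: no mean-variance trend, library quality weights, a pseudocount of 50 on the linear scale, the B cell list level as a covariate, and leaving out both TFH-labelled libraries with high B cell genes. Figures and remaining tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.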

Results

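Gene expression was measured in 8 mouse RNA sequencing libraries, 2 in each of 4 groups: naive WT, naive KO, TFH WT and TFH KO. KO donors lack C5aR1, a receptor for the complement fragment C5a, and TFH cells are the CD4 T cells that help B cells in germinal centres. Levels below are deposited log2 values, and changes are log2 differences of group means ± SE with n = 2 libraries per group. The depth of the libraries is unknown. C5ar1, the deleted gene, and its relatives C5ar2 and C3ar1 were not analysed here, so the genotype labels were not checked on the gene itself.

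Transcripts of Cxcr5 and Cd44, both sort markers, did not follow the surface patterns named in the labels. Cxcr5 lay between 11.56 and 12.45 in the 4 naive-labelled libraries and between 10.85 and 11.56 in the 4 TFH-labelled libraries. Cd44, a marker of antigen experience examined after its values were seen, was 12.53 to 13.04 in naive-labelled and 11.97 to 12.11 in TFH-labelled libraries. Pdcd1, which encodes the sort marker PD1, was 10.80 to 11.97 in naive-labelled and 11.88 to 12.85 in TFH-labelled libraries. Il21, the cytokine typical of TFH cells, was 7.31 to 8.19 in naive-labelled and 9.58 to 10.40 in TFH-labelled libraries. The groups are therefore called by their labels throughout.

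The first principal component held 67.9% of the variance and separated the labels, with naive-labelled libraries at 30.3 to 43.1 and TFH-labelled libraries at -38.2 to -31.7. Across genes, which are not independent replicates, Pearson's r between the 2 libraries of a group was 0.9829 in TFH KO and 0.9903 in TFH WT. Across genotypes it was 0.9924 between replicate 1 of TFH WT and of TFH KO and 0.993 between replicate 2 of each, above both within-group values. The median B cell gene lay 0.58 and 2.04 above its mean over all libraries in replicate 2 of TFH WT and of TFH KO, and at -1.70 and -1.74 in replicate 1 of each. Naive KO replicate 1 had Xist, the RNA of the inactive X chromosome, at 14.61 and the Y-linked Ddx3y at 5.67. In the other 7 libraries Xist was 4.44 to 5.56 and Ddx3y 12.54 to 13.16.

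**Figure D1:**
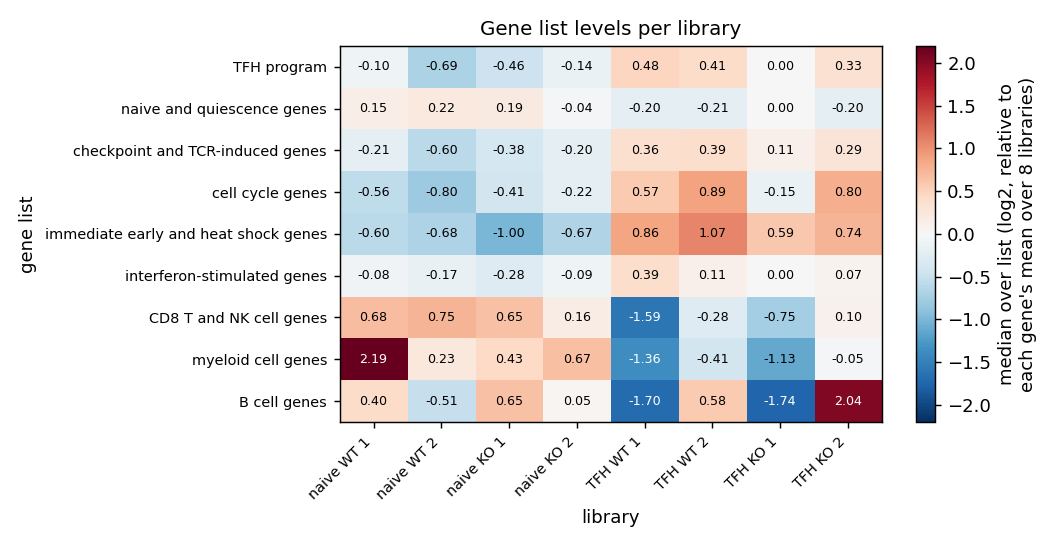
Median log2 level of each gene list (y axis) in each of the 8 libraries (x axis), relative to each gene's mean over the libraries, shown by color. The B cell genes range from -1.74 in TFH KO replicate 1 to 2.04 in TFH KO replicate 2, and the cell cycle genes from -0.80 in naive WT replicate 2 to 0.89 in TFH WT replicate 2.

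Libraries labelled TFH were compared with libraries labelled naive within WT, to ask what distinguished cells sorted on CXCR5 and PD1 after transfer. Tnfaip3, an inhibitor of NF-kB signalling, rose by 5.19 ± 0.11 (adjusted p = 2.58e-10), and the transcription factors Maff and Klf4 rose by 5.40 ± 0.15 and 4.99 ± 0.17. Among the genes with the largest falls were Paqr9 at -4.92 ± 0.53, the formyl peptide receptor Fpr1 at -4.88 ± 0.59 and the potassium channel gene Kcnj16 at -3.53 ± 0.27. Of 14042 genes, 3694 were called, 1772 higher and 1922 lower, and 1062 of them differed by a log2 of 1 or more.

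Of 28 measured genes of the TFH program, 13 rose, 1 fell and 14 were not called in WT. Il21 rose by 2.89 ± 0.24, the transcription factor gene Ascl2 by 2.71 ± 0.26, Il4 by 2.13 ± 0.26 and the surface molecule gene Cd200 by 1.44 ± 0.12. The list had 19 calls adjusted over the list alone. Camera with the preset correlation gave the list an adjusted p of 5.01e-07, against adjusted p = 0.532 with an estimated correlation. Fry gave it an adjusted p of 0.0268 for movement in 1 direction. Over all 25 lists fry called 8 in WT and 5 in KO. Bcl6, the master regulator of TFH cells, rose by 0.73 ± 0.19 (adjusted p = 0.0253). That call ended without naive WT replicate 2 (0.53, adjusted p = 0.13), TFH WT replicate 1 (0.71, adjusted p = 0.121) or TFH WT replicate 2 (0.74, adjusted p = 0.112). Cxcr5 at -0.57 ± 0.34, Pdcd1 at 1.36 ± 0.51, Icos at 0.80 ± 0.25 and Prdm1 at 0.60 ± 0.28 were not called. Without naive WT replicate 2, Cxcr5 was called at -1.01 (adjusted p = 0.0203), and without naive WT replicate 1, Icos was called at 1.15 (adjusted p = 0.00409). Prdm1 was called with the compared groups only (adjusted p = 0.00947) and with the B cell level as a covariate (0.68, adjusted p = 0.0285), and Icos with library quality weights (adjusted p = 0.0454); the covariate and the weights were chosen after seeing the data.

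Of 22 immediate early and heat shock genes, which respond to stimulation and stress within minutes, 18 rose and 4 were not called in WT. Fosb rose by 5.71 ± 0.41, Ppp1r15a by 3.42 ± 0.16 and Dusp1 by 3.14 ± 0.11. Of 20 checkpoint and T cell receptor-induced genes 12 rose and 2 fell, with Cd69 at 2.48 ± 0.10, Nr4a1 at 2.45 ± 0.10 and Nr4a2 at 3.67 ± 0.24. These lists had 19 and 16 calls adjusted over the list alone. Camera gave adjusted p-values of 2.15e-12 and 3.48e-04, against adjusted p = 0.165 and adjusted p = 0.532 with an estimated correlation, and fry gave 0.000415 and 0.00595. Of 40 cell cycle genes 34 rose, none fell and 6 were not called. The replication clamp gene Pcna rose by 1.33 ± 0.11 and the transcription factor gene E2f1 by 1.74 ± 0.21. The adjusted p was 1.06e-17 by camera, 0.532 with an estimated correlation and 0.0268 by fry. Adjusted over the list alone, 39 were called. The proliferation marker Mki67, at 1.77 ± 0.68, was not called, while Myc rose by 0.90 ± 0.14 (adjusted p = 0.000989). In the fit without the robust option, Pdcd1, Icos and Mki67 were called with adjusted p-values of 0.0272, 0.0286 and 0.026. Mki67 was also called with the B cell level as a covariate (1.96, adjusted p = 0.000277).

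Naive and quiescence genes moved both ways in WT: 14 of 28 fell and 4 rose. The interleukin 7 receptor gene Il7r, at -1.59 ± 0.15, and Txk, at -1.09 ± 0.11, fell, while the antiproliferative genes Tob1 and Btg1 rose by 1.55 ± 0.15 and 0.89 ± 0.10. There were 20 calls adjusted over the list alone. Camera gave 8.39e-04, against adjusted p = 0.532 with an estimated correlation and 0.0631 by fry. S1pr1, the receptor that lets T cells leave lymphoid tissue, fell by 0.59 ± 0.12 (adjusted p = 0.00408). Klf2, its transcriptional activator, rose by 0.52 ± 0.11 (adjusted p = 0.00646), a call that ended without naive WT replicate 1 (0.38, adjusted p = 0.0639) or TFH WT replicate 1 (0.47, adjusted p = 0.0528). Ccr7 at -0.03 ± 0.12 and Foxp3 at -0.15 ± 0.11 were not called.

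Some markers of cytotoxic and myeloid cells were called lower in TFH-labelled than in naive-labelled WT libraries. Of 14 CD8 T and NK cell genes 7 fell and none rose, with the NK receptor genes Klrb1c at -2.22 ± 0.12, Klrc1 at -2.84 ± 0.24 and Klrd1 at -2.51 ± 0.22. Of 24 Th1 and cytotoxic effector genes 10 fell and 1 rose, with the perforin gene Prf1 at -1.92 ± 0.13 and the chemokine receptor gene Cxcr6 at -2.57 ± 0.24. Of 26 myeloid genes 5 fell, none rose and 21 were not called, with Cd14 at -2.88 ± 0.36. Adjusted over the list alone, 8, 12 and 5 were called. Camera gave adjusted p-values of 1.76e-06, 0.0259 and 1.43e-07 for these lists. With an estimated correlation they had adjusted p = 0.532, adjusted p = 0.672 and adjusted p = 0.532, and by fry 0.0208, 0.135 and 0.0807. The Th1 list lost its camera call without naive WT replicate 1 (adjusted p = 0.143) or TFH WT replicate 1 (adjusted p = 0.0557). The median myeloid gene stood at 2.19 in naive WT replicate 1 and at 0.23 in naive WT replicate 2, against -1.36 and -0.41 in the TFH WT libraries. None of 22 B cell genes was called by limma over all genes or adjusted over the list alone, with a median change of -0.62. By camera the B cell list was called lower without TFH WT replicate 2 (adjusted p = 0.0141).

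Metabolic and interferon genes rose in part in WT. Of 30 amino acid, one-carbon and sterol genes 16 rose and 1 fell, with Psat1, an enzyme of serine synthesis, at 1.37 ± 0.13, and the transcription factor gene Atf4 at 1.28 ± 0.12. Of 35 interferon-stimulated genes 15 rose and 1 fell, with Mx2 at 1.55 ± 0.21. Of 23 glycolysis genes 8 rose and 2 fell, with Pgam1 at 0.94 ± 0.13 and Pdk1, which holds pyruvate back from the mitochondria, at -1.14 ± 0.13. Adjusted over the list alone, 20, 17 and 12 were called, and camera gave adjusted p-values of 6.52e-05, 0.00016 and 0.00362. Each list had adjusted p = 0.532 with an estimated correlation, and by fry they had 0.0147, 0.0631 and 0.0639. Of 76 oxidative phosphorylation genes 7 rose and 1 fell, and of 83 ribosomal protein genes 3 rose and 1 fell; adjusted over the list alone, 1 and 0 were called. Of 18 regulatory T cell genes 5 rose and 2 fell, with Ctla4 at 2.50 ± 0.23, and 11 were called adjusted over the list alone. Of 16 T cell identity genes 5 fell and 1 rose, with Thy1 at -0.99 ± 0.14 and Cd5 at -0.76 ± 0.12, and 6 were called adjusted over the list alone. The count of 3694 genes was 1991 without TFH WT replicate 2, 2298 without TFH WT replicate 1 and 2388 without naive WT replicate 2. It was 2104 without replicate 2 of both TFH groups, the libraries with high B cell genes, a setting chosen after seeing the data.

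The same comparison in KO asked whether TFH-labelled cells without C5aR1 differed from naive-labelled KO cells in the same genes. Tnfaip3 rose by 5.37 ± 0.11, Maff by 5.81 ± 0.15, Klf4 by 4.85 ± 0.17 and the insulin signalling gene Irs2 by 4.14 ± 0.19. The immunity-related GTPase gene Irgc1 fell by 4.08 ± 0.29, as did Rab6b at -2.91 ± 0.12 and Cxcr6 at -2.68 ± 0.24. Irgc1 was higher in naive KO than in naive WT (4.69), so its fall starts from a raised level. In all 2744 genes were called, 1280 higher and 1464 lower. Of these, 1000 higher and 1148 lower genes were also called in WT, against 161.5 and 200.4 for independent lists, and the pair of comparisons shares no library. Log2 changes had a Pearson's r of 0.876 and a Spearman's rho of 0.802 across genes.

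In KO, 10 of 28 TFH program genes rose and none fell, with Il21 at 1.93 ± 0.24, Ascl2 at 1.93 ± 0.26 and Cxcr4 at 1.07 ± 0.12. Of 40 cell cycle genes 11 rose, with Pcna at 1.15 ± 0.11, and of 22 immediate early and heat shock genes 17 rose, with Dusp1 at 2.97 ± 0.11. Calls adjusted over the list alone numbered 12, 11 and 17. Camera gave adjusted p-values of 1.28e-04, 5.03e-08 and 2.3e-17. With an estimated correlation they were 0.77, 0.77 and 0.0849, and by fry 0.168, 0.205 and 0.000397. Of 20 checkpoint and T cell receptor-induced genes 10 rose and 2 fell, with Nr4a1 at 2.66 ± 0.10, and of 30 amino acid, one-carbon and sterol genes 8 rose and 1 fell. The glutamine transporter gene Slc1a5 rose by 1.62 ± 0.10. Slc1a5 was lower in naive KO than in naive WT (-2.38), so this rise starts from a lowered level. These lists had 12 and 10 calls adjusted over the list alone. Both lists had a camera adjusted p of 0.00131, against adjusted p = 0.77 with an estimated correlation. By fry they had 0.0152 and 0.0266. Of 14 CD8 T and NK cell genes 4 fell, with Klrb1c at -1.66 ± 0.12, and of 24 Th1 and cytotoxic effector genes 8 fell and 1 rose, with Prf1 at -0.89 ± 0.13. Adjusted over the list alone, 4 and 11 were called. Camera gave 0.00667 and 0.0182, against adjusted p = 0.77 for both with an estimated correlation, and fry 0.188 and 0.205. Without TFH KO replicate 1 both camera calls were lost (adjusted p = 0.194 and 0.158), as was that of the Th1 list without naive KO replicate 2 (adjusted p = 0.272).

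Myc rose by 0.81 ± 0.14 in KO, and Klf2 by 0.52 ± 0.11, a call that ended without naive KO replicate 1 (0.46, adjusted p = 0.0525). Bcl6 at 0.62 ± 0.19 (adjusted p = 0.0579) was not called, but was without TFH KO replicate 1 (0.91, adjusted p = 0.00352). Cxcr5 at -1.04 ± 0.34, Pdcd1 at 0.58 ± 0.51, Icos at 0.23 ± 0.25 and Prdm1 at -0.19 ± 0.28 were not called either. Nor were Ccr7 at 0.33 ± 0.12, S1pr1 at -0.32 ± 0.12, Foxp3 at -0.15 ± 0.11 and Mki67 at 0.80 ± 0.68. Cxcr5 was called in the fits without the robust option (adjusted p = 0.031) and with the compared groups only (adjusted p = 0.00936). With the B cell level as a covariate, chosen after seeing the data, Bcl6 (0.65, adjusted p = 0.0063), Mki67 (0.91, adjusted p = 0.0111), Ccr7 (0.32, adjusted p = 0.0479) and S1pr1 (-0.33, adjusted p = 0.0483) were called. Klf2 was not called without replicate 2 of both TFH groups (0.53, adjusted p = 0.061). The count of 2744 genes was 1399 without TFH KO replicate 2, 1771 without naive KO replicate 2, and 1225 without replicate 2 of both TFH groups.

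**Figure D2:**
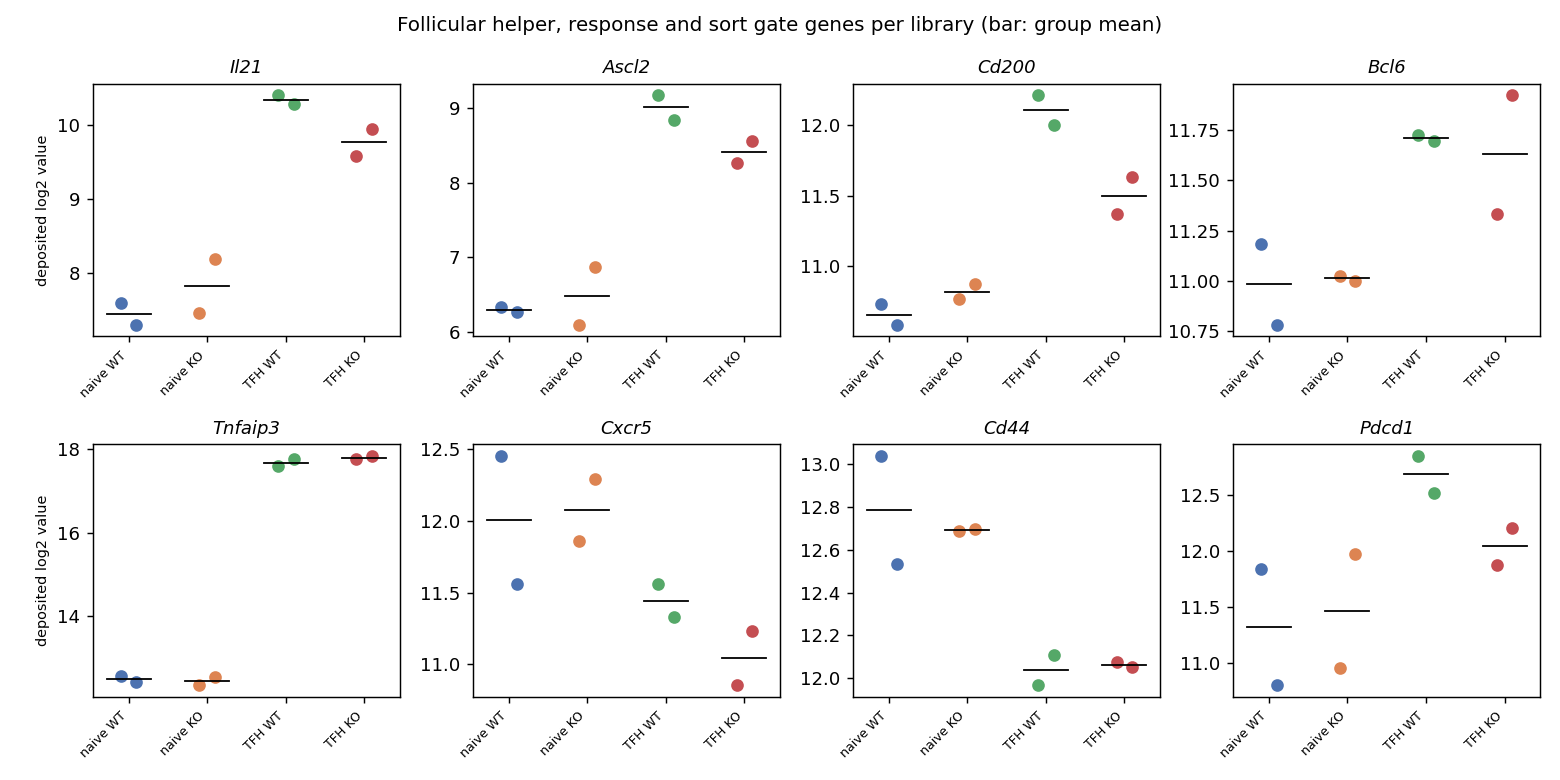
Deposited log2 values (y axis) of named genes in each library (points), by group (x axis, 2 libraries per group), with black bars at the group means. Il21 lies at 7.31 to 8.19 in the naive-labelled and 9.58 to 10.40 in the TFH-labelled libraries.

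The comparison of KO with WT among TFH-labelled libraries asks how loss of C5aR1 in the donor cells changed sorted TFH cells. No gene was called by limma. Cells of the F1 recipients among the sorted cells, weighed below, stay open and would lessen differences between donor genotypes. The smallest p-values among named genes were those of Slc1a5 at -0.62 ± 0.10 (adjusted p = 0.475), the complement regulator gene Cd55 at 0.68 ± 0.13 (adjusted p = 0.751) and the helicase gene Dhx34 at 0.65 ± 0.12. Slc1a5 and Dhx34 are neighbours of C5ar1 on chromosome 7. At an unadjusted p below 0.05 there were 506 genes. With the compared groups only, limma called 1 gene, Hspa1b, a heat shock gene chosen after its values were seen, at -3.87 ± 0.24 (adjusted p = 0.000824).

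The TFH program genes were mostly lower in KO, with 4 of 28 differences positive, a median of -0.40 and none called over all genes. Adjusted over the list alone, 2 were called, Cd200 at -0.60 ± 0.12 and Tox, a transcription factor gene of TFH differentiation, at -0.42 ± 0.11. Camera gave 8.59e-08, against adjusted p = 0.578 with an estimated correlation. All 40 cell cycle genes had negative differences, with a median of -0.43, as in Mcm6 at -0.50 ± 0.14, and none was called adjusted over the list alone. Of 35 interferon-stimulated genes 6 had positive differences, with Ifih1 at -0.44 ± 0.10 and Isg15 at -0.79 ± 0.18 called adjusted over the list alone. Camera gave 6.25e-15 and 1.09e-09 for these lists, against adjusted p = 0.578 for both with an estimated correlation. The median cell cycle gene stood at 0.57 and 0.89 in the TFH WT libraries, at 0.80 in TFH KO replicate 2 and at -0.15 in TFH KO replicate 1. Without TFH KO replicate 1 the camera call of the cell cycle list was lost (adjusted p = 0.959). The median TFH program gene stood at 0.48 and 0.41 in TFH WT, and at 0.00 and 0.33 in TFH KO. Glycolysis genes, with 4 of 23 differences positive, and regulatory T cell genes, with 5 of 18, were also mostly lower. Camera gave them adjusted p-values of 6.71e-06 and 0.00271, against 0.578 and 0.618 with an estimated correlation. The camera calls of both, of the TFH program and of the interferon-stimulated genes held with each library left out in turn. All 14 CD8 T and NK cell genes were higher, with Klrc1 at 0.79 ± 0.24 and a median of 0.57, and 23 of 28 naive and quiescence genes were higher, with Il7r at 0.49 ± 0.15. Camera gave 1.79e-06 and 0.000697, against adjusted p = 0.578 and adjusted p = 0.618 with an estimated correlation, and neither list had a gene called adjusted over the list alone. These camera calls were lost without TFH WT replicate 1 (adjusted p = 0.434) or TFH KO replicate 2 (adjusted p = 0.156) for the CD8 T and NK cell list, and without TFH KO replicate 1 for the naive list (adjusted p = 0.432). B cell genes, at a median of 0.70, were higher in 21 of 22 cases (adjusted p = 0.0145 by camera, adjusted p = 0.762 with an estimated correlation). Their direction reversed without TFH KO replicate 2 (adjusted p = 7.32e-09) or TFH WT replicate 1 (adjusted p = 0.138).

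The following genes, fixed for every comparison, were not called between TFH KO and TFH WT. Bcl6 differed by -0.08 ± 0.19, Cxcr5 by -0.40 ± 0.34, Pdcd1 by -0.64 ± 0.51, Icos by -0.41 ± 0.25, Il21 by -0.58 ± 0.24 and Prdm1 by -0.47 ± 0.28. Ccr7 differed by 0.26 ± 0.12, S1pr1 by 0.19 ± 0.12 and Klf2 by 0.08 ± 0.11. Foxp3 differed by -0.02 ± 0.11, Myc by 0.11 ± 0.14 and Mki67 by -0.50 ± 0.68. Fry called 0 of 25 lists for movement in 1 direction, with a smallest adjusted p of 0.77, and 2 by its mixed test, the amino acid, one-carbon and sterol genes and the neighbours of C5ar1 (adjusted p = 0.0219 for both), which share Slc1a5. Camera with an estimated correlation called 0. Limma also called 0 genes with each library of this comparison left out in turn.

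The comparison of KO with WT among naive-labelled libraries served as the side-by-side control of genotype, in cells for which the labels name no transfer. Of 14042 genes 10 were called, 5 higher and 5 lower, and all 10 lie in the first 40 Mb of chromosome 7, a window set after their positions were seen. The gene with the smallest adjusted p, Slc1a5 (chromosome 7, 16781340 to 16798274, GRCm38), fell by 2.38 ± 0.10 (adjusted p = 7.13e-07), from 13.97 to 11.59. Irgc1 (24431922 to 24452297) rose by 4.69 ± 0.29 (adjusted p = 1.79e-05) and the F-box gene Fbxo17 (28716804 to 28738144) by 2.09 ± 0.13. C5ar1 itself lies at 16246743 to 16259540 of that chromosome.

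Also lower were the laminin receptor gene Bcam at -1.99 ± 0.23, the zinc finger gene Zfp974 at -1.75 ± 0.19 and Ccdc61 at -1.47 ± 0.14. Also higher were Fbxo27 at 1.81 ± 0.21 and Sae1, which encodes a subunit of the SUMO-activating enzyme, at 0.74 ± 0.09. The remaining pair, Zfp30 at 2.70 ± 0.32 and Gm19897 at -1.50 ± 0.20, fell outside the naming rule and was chosen after the values were seen. Of 25 measured neighbours of C5ar1, 1 rose and 1 fell, and 3 were called adjusted over the list alone. Bcam was no longer called without naive WT replicate 1 (-1.78, adjusted p = 0.0805), nor was Fbxo27 without it (1.77, adjusted p = 0.0805) or without naive KO replicate 1 (1.70, adjusted p = 0.0686). Sae1 lost its call without naive WT replicate 1 (0.77, adjusted p = 0.0805), naive WT replicate 2 (0.71, adjusted p = 0.0787), naive KO replicate 1 (0.75, adjusted p = 0.0673) or naive KO replicate 2 (0.73, adjusted p = 0.0535). It also lost it with the compared groups only (adjusted p = 0.0529), without replicate 2 of both TFH groups (adjusted p = 0.0534) and, like Fbxo27 (adjusted p = 0.0692), without a mean-variance trend (adjusted p = 0.136). Without naive WT replicate 2, 17 genes were called.

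The heat shock genes Hspa1a and Hspa1b, at -7.20 ± 1.42 and -6.53 ± 1.38, were not called in naive-labelled libraries. Both were called without naive WT replicate 1 (-9.19, adjusted p = 4.16e-05, and -8.44, adjusted p = 0.000483) and without naive WT replicate 2 (-5.21, adjusted p = 0.00321, and -4.62, adjusted p = 0.0146). Of 28 TFH program genes 1, Cxcr4 at -0.69 ± 0.12 (adjusted p = 0.0741 over all genes), was called adjusted over the list alone. Cell cycle genes had 37 of 40 positive differences and myeloid genes 2 of 26, and neither list had a gene called adjusted over the list alone. Camera gave 5.78e-09 and 9.98e-07, against adjusted p = 0.718 for both with an estimated correlation, and the myeloid direction reversed without naive WT replicate 1 (adjusted p = 0.463). Bcl6 differed by 0.03 ± 0.19, Cxcr5 by 0.07 ± 0.34, Pdcd1 by 0.14 ± 0.51, Icos by 0.17 ± 0.25, Il21 by 0.38 ± 0.24 and Prdm1 by 0.32 ± 0.28. Ccr7 differed by -0.10 ± 0.12, S1pr1 by -0.08 ± 0.12 and Klf2 by 0.08 ± 0.11. Foxp3 at -0.01 ± 0.11, Myc at 0.20 ± 0.14 and Mki67 at 0.47 ± 0.68 were not called, nor were the other genes of this set given above.

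**Figure D3:**
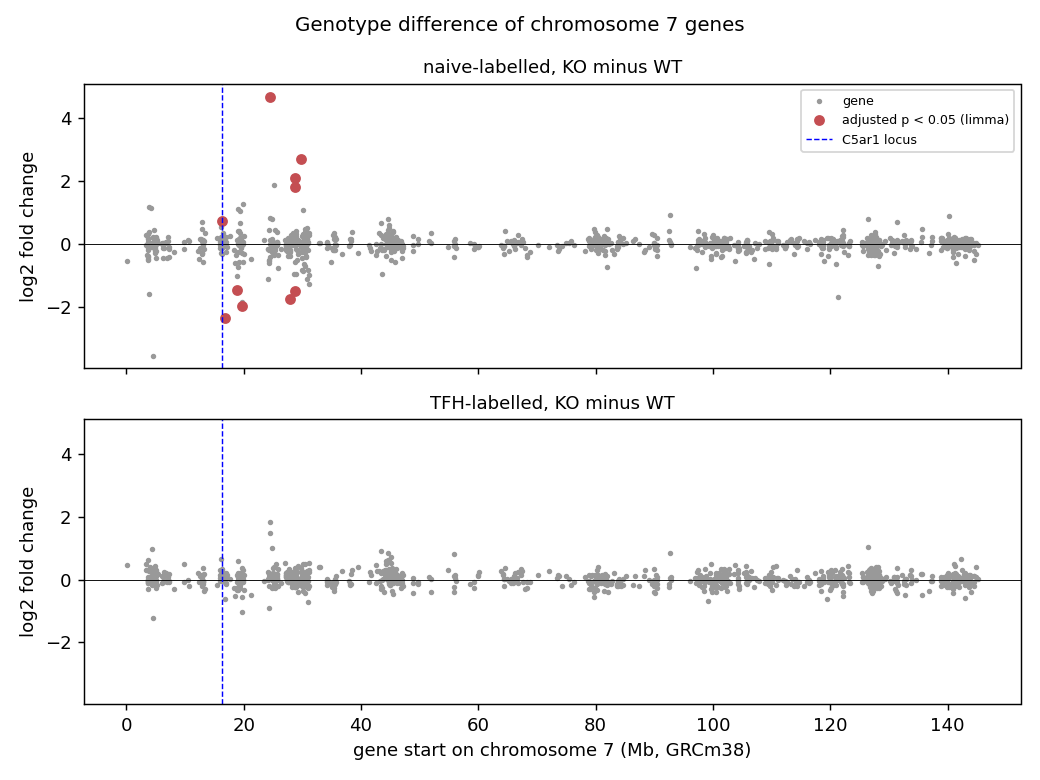
Log2 fold change of KO against WT (y axis) by gene start on chromosome 7 in Mb (x axis, GRCm38), in naive-labelled (top) and TFH-labelled (bottom) libraries; red points are genes called by limma and the dashed line marks the C5ar1 locus. The called genes of the naive-labelled comparison run from -2.38 for Slc1a5 to 4.69 for Irgc1, all in the first 40 Mb.

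The interaction asks whether the KO against WT difference itself differed between TFH-labelled and naive-labelled libraries. Slc1a5 gave 1.75 ± 0.15 (adjusted p = 0.000954), with a KO against WT difference of -2.38 in naive-labelled and -0.62 in TFH-labelled libraries. Fbxo17 gave -1.71 ± 0.19 (adjusted p = 0.00959), with differences of 2.09 and 0.38. These were the 2 genes called, and 614 had an unadjusted p below 0.05. Without a mean-variance trend, a setting chosen after seeing the data, neither was called (adjusted p = 0.109 for both). Fbxo17 also lost its call without TFH WT replicate 1 (-1.72, adjusted p = 0.0642), TFH WT replicate 2 (-1.69, adjusted p = 0.0734) or TFH KO replicate 1 (-1.68, adjusted p = 0.0611), and without replicate 2 of both TFH groups (-1.72, adjusted p = 0.134).

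Of the genes fixed for every comparison, Il21 at -0.96 ± 0.33, Pdcd1 at -0.78 ± 0.73, Prdm1 at -0.79 ± 0.39 and Icos at -0.57 ± 0.36 were not called in the interaction. Bcl6 at -0.11 ± 0.27, Cxcr5 at -0.47 ± 0.48, Ccr7 at 0.36 ± 0.16 and S1pr1 at 0.27 ± 0.17 were not called. The same held for Klf2 at 0.01 ± 0.16, Foxp3 at 0.00 ± 0.15, Myc at -0.09 ± 0.20 and Mki67 at -0.97 ± 0.96. All 40 cell cycle genes gave negative interaction values, with a median of -0.74, and all 14 CD8 T and NK cell genes positive ones, with Klrc1 at 1.38 ± 0.34. The counts adjusted over the list alone were 0 and 3. Camera gave 1.44e-18 and 9.73e-08, against adjusted p = 0.698 for both with an estimated correlation. Across genes, the KO against WT differences of TFH-labelled and naive-labelled libraries had a Pearson's r of -0.021 and a Spearman's rho of -0.184.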

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

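The interaction tests, the list tests with camera and fry, and leaving out each library were planned; the tests of the explanations weighed below, and the way the planned fits are read for them, were chosen after the results were seen. The difference between KO and WT differed between TFH-labelled and naive-labelled libraries for Slc1a5 (interaction 1.75 on the log2 scale) and Fbxo17 (-1.71). Both genes lie in the first 40 Mb of chromosome 7, weighed below.

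By camera with the preset correlation, the interaction also passed for 12 of 25 lists. Adjusted p-values were 1.44e-18 for cell cycle genes, 9.73e-08 for CD8 T and NK cell genes, 2.64e-06 for oxidative phosphorylation genes, and 3.81e-06 for both myeloid genes and naive and quiescence genes. They were 0.000441 for the TFH program, 0.000608 for glycolysis genes, 0.0071 for interferon-stimulated genes and 0.0174 for regulatory T cell genes. Ribosomal protein genes gave 0.0179, amino acid, one-carbon and sterol genes 0.0321, and erythroid and platelet genes 0.0406. None of the 12 passed with an estimated correlation (smallest adjusted p = 0.698) or by fry for movement in 1 direction (smallest adjusted p = 0.769). By fry's mixed test, for change in either direction, the amino acid, one-carbon and sterol genes, which include Slc1a5, passed at 8.79e-07. With each library left out in turn, 3 of the 12 kept their call: cell cycle genes, CD8 T and NK cell genes, and naive and quiescence genes.

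The 10 calls between naive-labelled KO and WT libraries lie in the first 40 Mb of chromosome 7, which holds C5ar1. The sex of naive KO replicate 1 is argued against, since 6 of the 10 stayed called in a fit without that library and all 10 differences kept their direction, at 5.50 to 18.31 SE from 0, and B cell content is too, since 10 of 10 stayed called with the B cell level as a covariate. Without that library the other 4 lost their calls while their SE grew with 1 library fewer: Fbxo27 from 1.81 ± 0.21 to 1.70 ± 0.27, Gm19897 from -1.50 ± 0.20 to -1.31 ± 0.24, Sae1 from 0.74 ± 0.09 to 0.75 ± 0.12 and Zfp30 from 2.70 ± 0.32 to 2.77 ± 0.42. A candidate explanation is a segment of another strain carried along with the deletion: of the 90 genes ranked next by p, 29 lay in the window against 2.3 by chance (one-sided exact p = 3.07e-24). Loss of C5aR1 itself stays open and untested for these genes.

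Of the MHC region genes examined, H2-Ea-ps (8.21 to 12.44 against at most 1.79) and H2-Q2 (11.72 to 12.11 against 8.66 to 8.98) were higher in all 4 TFH-labelled libraries, as were Gm8909 (at least 10.54 against at most 7.54) and Gm11127 (9.59 to 9.93 against 6.89 to 7.33), while H2-Eb1 overlapped (9.21 to 13.44 against 10.89 to 12.34); all but H2-Ea-ps were picked after their values were seen. The amount of B cells alone is argued against, because H2-Ea-ps minus H2-Eb1 was at least 8.08 higher in every TFH-labelled than in every naive-labelled library, on the log2 scale. Cells of the F1 recipients among the sorted cells stay open. Over the 10 called chromosome 7 genes, the slope of TFH-labelled on naive-labelled genotype differences was 0.263 (0.179 to 0.291 with each gene left out). These genes were picked for a large naive-labelled difference, which favours a slope under 1. The interaction was nonetheless called for Slc1a5 and Fbxo17 in the main fit. Recipient cells and another substrain of donors could both lower the slope, so it does not tell them apart. Another substrain of donors for these libraries also stays open. Over the 10 called chromosome 7 genes, TFH WT lay at a median position of 0.292 between naive WT and naive KO, ranging from -0.258 to 0.767. Recipient cells could give such a position too, so it decides nothing, and it covers none of the MHC region genes. The labels say that donor cells were sorted, which would remove recipient cells. In TFH-labelled replicate 1 of WT and KO, H2-Ea-ps was 8.22 and 8.21, with H2-Eb1 at 9.21 and 9.23. In replicate 2, with more B cell genes, they were 11.03 and 12.44, with H2-Eb1 at 12.05 and 13.44. For H2-Ea-ps, following H2-Eb1 in this way argues against an effect of TFH differentiation alone. H2-Q2, at 11.72 to 12.11, did not follow H2-Eb1. An effect of TFH differentiation on H2-Q2, Gm8909, Gm11127 and the chromosome 7 genes stays open and untested.

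The transcripts of Cxcr5 and Cd44 did not follow the sort labels. An exchange of the naive and TFH labels is argued against, since TFH program genes that rose outnumbered those that fell by at least 10 in both WT and KO. Cells of other types in the naive-labelled libraries could add to the pattern: 19 calls of myeloid or CD8 T and NK cell genes fell and 0 rose over both genotypes, but the lists had adjusted p up to 0.77 with an estimated correlation, which keeps this open, and the labels say that CD4 T cells were sorted, which would remove such cells. Handling that differed between the sorts cannot be told apart from the labels, because 18 of 22 immediate early and heat shock genes were higher in every TFH-labelled than in every naive-labelled library. A change of these transcripts with TFH differentiation itself stays open.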

How the results depend on the processing

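No trend, library weights, the pseudocount, the B cell covariate and leaving out both B cell-rich TFH libraries were chosen after seeing the data; the others were planned. DESeq2, voom and RLE scaling need counts and were not run, and no filter is the setting used throughout. No paired analysis was possible because the labels give no replicate numbers; those used here follow the order of deposit. Of 416 named gene values, of which 210 were called, 0 reversed under any alternative; 38 calls appeared and 230 were lost over all settings. With the compared groups only, 1 gene was called between TFH KO and WT. For TFH against naive labels, WT and KO counts were 2104 and 1225 without both B cell-rich libraries (fewer libraries), 1980 and 1347 at an adjusted p below 0.01, and 1062 and 704 at a log2 change of 1 or more. Without the trend the interaction called 0 genes; the cause was not tested. Leaving out each library in turn gave 7 to 17 calls for naive KO against WT, 1991 to 2501 and 1399 to 2219 for the labels in WT and KO, and 1 to 7 for the interaction. Unknown depth leaves the error of low genes open.

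List directions by camera that reversed without some library had these adjusted p ranges over the fits with each library left out. The ranges pool both directions, and the cause was not tested. With all libraries, camera gave the TFH program an adjusted p of 0.938 between naive KO and WT. Between TFH KO and WT they were 6.52e-28 to 0.138 for B cell, 6.99e-09 to 0.152 for myeloid, 1.55e-05 to 0.584 for plasma cell and 0.000339 to 0.856 for ribosomal protein genes. Between naive KO and WT they were 0.000184 to 0.00894 for the TFH program, 7.45e-08 to 0.169 for Th1, 0.0045 to 0.308 for checkpoint, 5.56e-05 to 0.768 for erythroid, 1.86e-05 to 0.701 for interferon-stimulated, 1.43e-21 to 0.463 for myeloid and 1.84e-13 to 0.555 for oxidative phosphorylation genes. For TFH against naive labels in KO, B cell genes gave 7.63e-07 to 0.883. For the interaction they were 1.93e-13 to 0.979 for B cell, 0.0003 to 0.748 for Th1, 0.000318 to 0.979 for plasma cell and 2.18e-05 to 0.979 for ribosomal protein genes.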

Other observations

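The test in this part was chosen after the result was seen, on genes picked for their separation. The inducible heat shock genes Hspa1a and Hspa1b, which encode HSP70 chaperones, were lower in all 4 KO libraries than in all 4 WT libraries, over both labels. The mean difference was -5.45 for Hspa1a and -5.20 for Hspa1b on the log2 scale. The lowest WT library was at 9.72 for Hspa1b and the highest KO library at 6.30; for Hspa1a the highest KO library was at 5.71. An exact two-sided permutation within labels cannot go below p = 0.056 with its 36 splits, the value both genes have by the way they were picked, so it decides nothing. The genes are near-identical copies whose reads the authors' counting could split between them, so their separate levels are uncertain. Hspa1b lies on chromosome 17 (34956436 to 34959238, GRCm38), on another chromosome than C5ar1. A strain difference at that locus and handling that differed between the sorts were not tested for these genes.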
